A study of Mus musculus with 12 samples.

How the data were processed

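Gene expression was measured in whole pancreatic tumours of female C57BL/6J mice. Per the labels, syngeneic pancreatic tumour cells in Matrigel were implanted surgically into the pancreas, and mice with established tumours received through their chow either vehicle (Vehicle) or an inhibitor of the colony-stimulating factor 1 receptor (CSF1Ri) for 8 days. The animals were perfused with heparinised saline, the tumours were digested with collagenase, and kit-extracted, DNase-treated total RNA was amplified to biotin-labelled cRNA. The compound and its dose are not given in the sources used here.

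The series holds 12 Illumina BeadArrays from 9 tumours, 4 Vehicle and 5 CSF1Ri. The titles of 3 arrays repeat those of Vehicle 1, Vehicle 3 and CSF1Ri 1 with a mark for a second hybridisation, read here as repeats on the same tumours, so the tumour was taken as the replicate and the arrays of a tumour were averaged. Groups came from the treatment label of each sample and replicate numbers from its title.

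Per the file headers, the authors deposited a probe intensity and a detection p-value for each of 45281 probes on each array. The deposited intensity was already background-subtracted, because it falls to negative values, and it was not scaled between arrays. The detection p-value, per the file headers, belongs to the same probe and array and is read here as the test against the negative controls of that array. A further deposited table holds the authors' processed intensity on a linear scale. Each of its columns equals the unscaled column times 1 factor, from 0.672 to 1.49, which gives every array a mean of 212.02, and column medians lay between 3.61 and 5.35. The factor was constant within an array to a relative deviation of 9.52e-07 among intensities over 100, so the scale (linear) and the absence of centring were settled from the values. The software for scanning, background subtraction and scaling is not given in the sources used here.

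From the unscaled intensities, limma 3.58.1 in R 4.3.3 was run as neqc, which models the background from the detection p-values, adds an offset of 16, applies quantile normalization over the 12 arrays and takes log2. A probe was kept when its detection p-value was under 0.05 on every array of a tumour in at least 4 tumours. This left 16606 probes. The probe annotation gave 34885 probes 1 gene symbol, 18 several and 10378 none, and 14378 kept probes had a single symbol. Symbols were checked through Entrez identifiers against a RefSeq gene table, which held 34807 of the probes and changed 0 symbols. A probe without a symbol is unnamed here, and genes that only such probes or dim probes report were not analysed here. Where several kept probes named a gene (3307 genes), the probe with the highest mean over the tumours stood for it, which gave 9788 genes. No genome build is named in the sources used here, so no coordinates are given.

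The groups were compared with limma (lmFit and eBayes with default settings, no covariate), with Benjamini-Hochberg adjustment over the 9788 genes and a threshold of 0.05. A log2 fold change is CSF1Ri minus Vehicle, and its standard error (SE) is the moderated SE of the fit. Fold changes of dim genes are understated by the offset. A probe detected on no array of a group has only a bound there. Its fold is given as "at least", with the brighter group's mean set against the higher of the probe's own value and the lowest detected signal of each array in the dimmer group.

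Before the data were examined, 40 gene lists of cell types and pathways were written from general knowledge, and 35 had at least 5 members tested. The 5 others were plasmacytoid dendritic cells (4 of 8 members tested), regulatory T cells (4 of 10), adipocytes (2 of 13), skeletal muscle (3 of 14) and mesothelium (4 of 8). Each list was tested with camera from limma at a preset inter-gene correlation of 0.01, which compares the list with all other genes, with Benjamini-Hochberg adjustment over the 35 lists. It was tested again with camera at an estimated correlation and with fry, a test of whether the members move on balance in 1 direction. A two-sided exact permutation test of the list mean over all 126 splits of the 9 tumours was also made, whose smallest possible p is 0.00794. Adjustment over the 35 lists can bring such a p under 0.05 only when several lists have similarly small values. A list whose groups separate fully can therefore miss the threshold in this test. The number of members past 0.05 is given over all genes and adjusted over the list alone. Of the 746 distinct genes in the lists, 512 were tested and 15 stood in more than 1 list. At the preset correlation, camera treats the members of a list as nearly independent. Members of many of these lists vary together between tumours, and the result with an estimated correlation is given beside each call and the permutation beside most.

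The named genes follow a rule that was also fixed before the data were examined. It takes Csf1r, Csf1 and Il34, then the 12 lowest and 12 highest log2 fold changes among called genes whose groups do not overlap, with free places filled by the smallest unadjusted p and given as values only, and then up to 4 members of each list, called members before the others and then by unadjusted p. Genes outside it are said to have been chosen after their values were seen.

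Signal limits these arrays. Mean unscaled intensity ran from 142 to 316 per array, between 16219 and 17847 probes (35.8% to 39.4%) were detected, and the number of tumours limits the precision. Repeat arrays of a tumour correlated at 0.988 to 0.993 over the tested genes, against a median of 0.969 and a highest value of 0.985 for arrays of different tumours (correlations across genes, which are not independent). The median absolute log2 difference between repeats was 0.137 for Vehicle 1, 0.169 for Vehicle 3 and 0.175 for CSF1Ri 1. For arrays of different tumours its median was 0.246 and its lowest value 0.158, so by this measure the ranges overlapped. The labels and files name no slide or scan batch. The 3 repeat arrays were brighter than the first arrays of the same tumours. The 12 arrays were therefore also divided, after the data were seen, into 6 at least as bright as the dimmest repeat array (mean 223.7 or more) and 6 dimmer (mean 193.4 or less), each with 3 Vehicle and 3 CSF1Ri tumours. Vehicle 1, Vehicle 3 and CSF1Ri 1 have arrays in both sets, so the sets are not independent. Vehicle 2, CSF1Ri 2 and CSF1Ri 3 are only in the dimmer set, and Vehicle 4, CSF1Ri 4 and CSF1Ri 5 only in the brighter set. A difference between the sets can therefore come from the tumours in them as well as from brightness, and the values below do not separate these.

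The fit was tested on simulated data with the means and variances of the 9788 genes, 4 against 5 tumours and 200 changed genes, 20 times. It called 78.5% of genes changed 2-fold and 96.6% of genes changed 4-fold, all in the right direction, and 5.05% of the calls were false. These simulated genes were independent of each other, unlike real genes. In the list step, a macrophage list shifted by -0.50 was called in 100% of 20 simulations and unchanged lists in 0.625%, again with independent genes.

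Other settings were also tried. They covered background correction, normalization, the authors' processed values, the filter, the treatment of repeat arrays, the variance model, array weights, the replicate number as a block, the acinar list as a covariate, the summary of probes, other thresholds and list tests, and leaving out each tumour. Alternatives by array brightness were chosen after seeing the data.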

Results

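Whole orthotopic pancreatic tumours from 4 mice given vehicle (Vehicle) and 5 given a CSF1R inhibitor (CSF1Ri) through their chow were profiled on 12 Illumina BeadArrays after 8 days. Macrophages and their precursors depend on CSF1R, the receptor for Csf1 and Il34. The comparison asks how blocking this receptor alters gene expression in the tumour as a whole, which mixes tumour cells, stroma, immune cells and residual pancreas. Values are normalised log2 intensities per tumour, as mean ± SD, with n = 4 for Vehicle and n = 5 for CSF1Ri unless stated. Between 16219 and 17847 of 45281 probes were detected per array, and 9788 named genes were tested.

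Csf1r marks monocytes and macrophages. Csf1r itself (Entrez Gene 12978) was 7.46 ± 0.29 in Vehicle and 6.24 ± 0.32 in CSF1Ri tumours, a 2.32-fold fall (log2 fold change -1.22, SE 0.19, limma adjusted p = 0.0345). Its call was lost when any tumour other than Vehicle 1 or CSF1Ri 3 was left out (log2 fold changes -1.25 to -1.09, adjusted p up to 0.142). It was also lost in the authors' processed values, without the filter on dim probes, with repeat hybridisations left out, with the acinar covariate and within the dimmer arrays (adjusted p = 0.108, 0.0980, 0.115, 0.0823 and 0.639). The replicate number as a block removed the call of Csf1r too. Its log2 fold change was negative under all 25 alternatives run, from -1.47 to -0.81. The ligands gave no call. Csf1 was 6.45 ± 0.52 and 6.75 ± 0.46 (adjusted p = 0.912), and Il34 was 7.87 ± 0.17 and 7.98 ± 0.24 (adjusted p = 0.960). Without Vehicle 1 the log2 fold change of Csf1 went from 0.30 to 0.07.

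Over all 9788 genes, 21 were lower and 0 were higher in CSF1Ri tumours at an adjusted p under 0.05 (limma), and the values of the groups did not overlap for any of the 21. Their falls ran from 1.78-fold to 9.63-fold. At an unadjusted p under 0.05, 372 genes were lower and 365 higher, where 489 in all would be expected by chance. The groups did not overlap for 139 lower and 143 higher genes, 2.88% of those tested against 1.59% by chance. The smallest adjusted p of a higher gene was 0.0556, for Itpk1. Other limma settings called up to 6 higher genes, the most in an alternative by array brightness that was chosen after seeing the data. The count of lower genes fell to 1 (Cx3cr1) within the 6 dimmer arrays (3 against 3 tumours) and to 11 within the 6 brighter arrays.

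Among the called genes were 2 secreted proteases with large falls. Mmp9, a gelatinase of neutrophils, macrophages and osteoclasts, went from 10.73 ± 0.47 to 7.47 ± 0.40 (9.63-fold, adjusted p = 0.000434). Ctsk, the collagen-degrading cathepsin K, went from 11.81 ± 0.59 to 8.67 ± 0.61 (8.84-fold, adjusted p = 0.00451). Cx3cr1, the fractalkine receptor of monocytes and macrophages, had the smallest adjusted p, with 7.27 ± 0.11 against 4.72 ± 0.23 (adjusted p = 1.63e-05). It was detected on 6 of 6 Vehicle arrays and 1 of 6 CSF1Ri arrays. Its log2 fold change ran from -3.05 to -1.49 (offset of 50 with another background model) over the alternatives, with the call kept. Fcrls, an Fc receptor-like gene, was by its brighter kept probe detected on 0 of 6 CSF1Ri arrays and at least 4.19-fold lower (adjusted p = 0.00451). The monocyte chemoattractant Ccl12 fell 5.07-fold and the cation exchanger gene Slc9b2 fell 3.90-fold, the latter detected on 2 of 6 CSF1Ri arrays. The remaining genes among the 12 lowest fell between 2.50-fold and 2.90-fold. They were Ms4a7 and Ms4a6d, membrane proteins of macrophages, the purinergic receptor gene P2ry13, the mannose receptor gene Mrc1, the endosomal receptor gene Tlr13, and Tmem273 (detected on 5 of 6 CSF1Ri arrays). Another setting had a larger offset of 50 and a background model that does not use the detection p-values. With it the log2 fold changes of the dimmer genes here were smaller and their calls were kept: Fcrls -1.42 (from -2.47), Slc9b2 -1.08 (from -1.96), P2ry13 -0.85 (from -1.43), Tlr13 -0.70 (from -1.32) and Tmem273 -0.72 (from -1.32). The other kept probe was at -0.38 for Tlr13, -1.75 for Fcrls and -0.78 for Tmem273.

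The other called genes fell 1.78-fold to 2.47-fold. By list membership these were the complement gene C6, the monocyte lectin gene Clec4a1, Spi1, which encodes the myeloid transcription factor PU.1, and the amplifying receptor gene Trem1. Cd33, Gm5150, Ntpcr and Oscar complete the 21 and were chosen for mention after their values were seen. All of these but Ntpcr were dim, and C6 and Oscar were detected on 2, Cd33 on 1, Spi1 on 3, Clec4a1 and Trem1 on 4 and Gm5150 on 5 of 6 CSF1Ri arrays. With the offset of 50 and its other background model, the log2 fold changes of these dim genes were between -0.65 (Oscar) and -0.43 (Spi1). C6, Clec4a1, Spi1 and Oscar lost their calls there. Of the 21 genes, 10 kept their call whichever single tumour was left out: Cx3cr1, Mmp9, Ctsk, Mrc1, Fcrls, P2ry13, Slc9b2, Ms4a6d, Trem1 and Cd33.

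**Figure D1:**
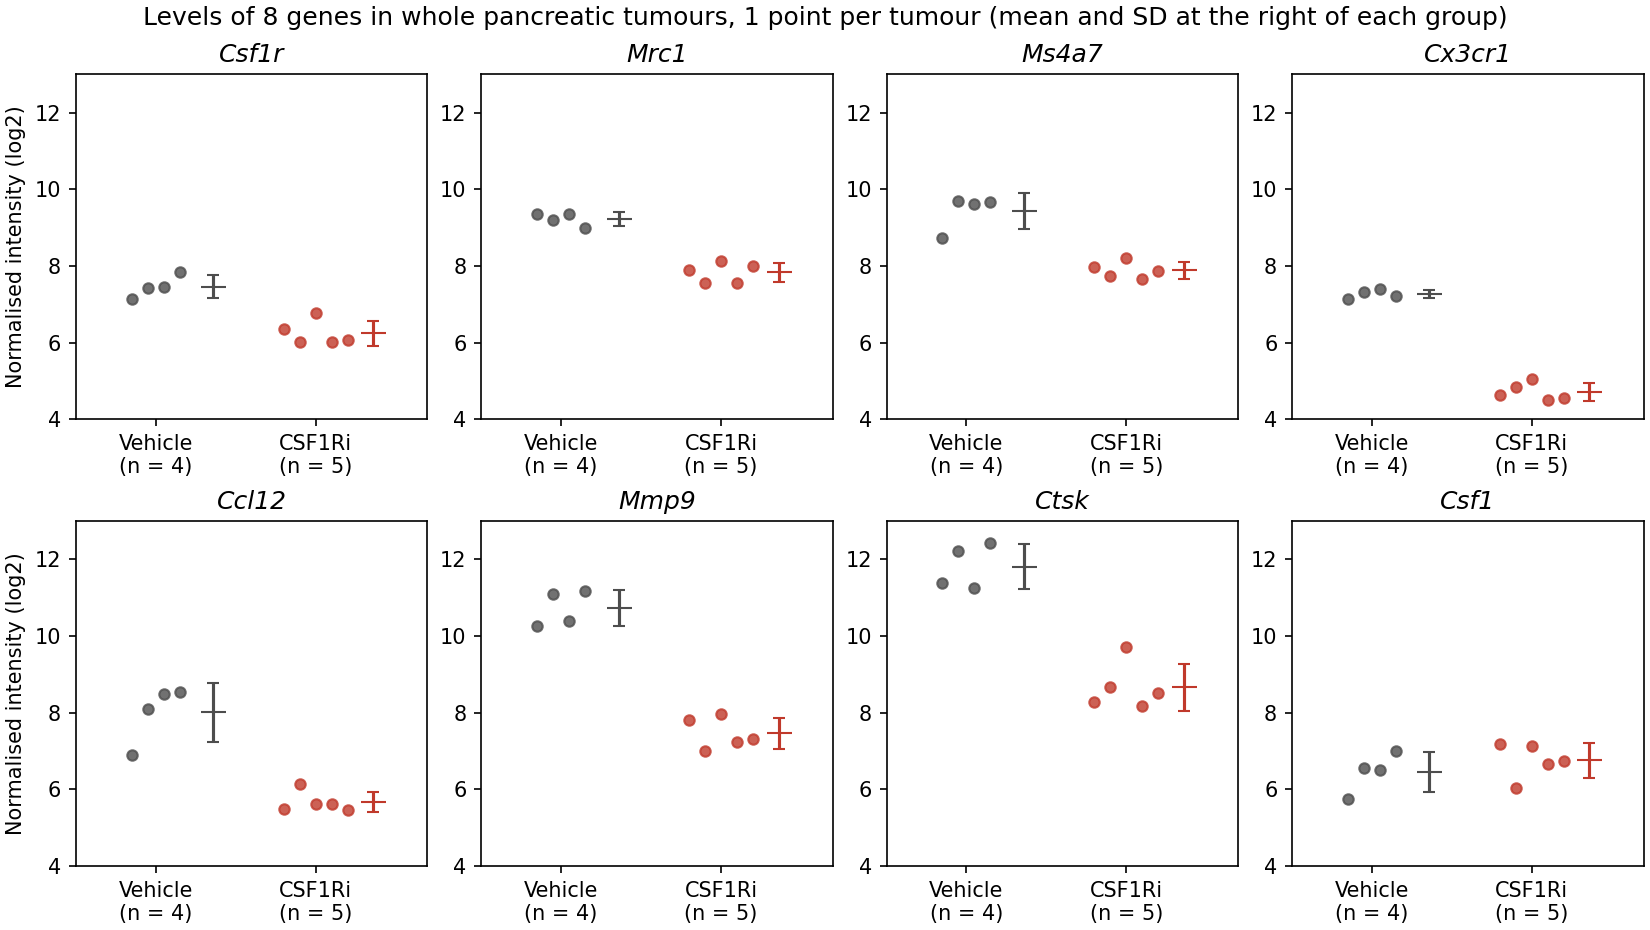
Normalised log2 intensity (y axis) of 8 genes in each Vehicle (grey, n = 4) and CSF1Ri (red, n = 5) tumour, with the mean and SD beside each group. Cx3cr1 was at 7.27 ± 0.11 in Vehicle and 4.72 ± 0.23 in CSF1Ri tumours with no overlap, whereas Csf1 values overlapped.

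Of 35 gene lists, camera at the preset correlation called 5 higher and 16 lower, camera with an estimated correlation called 1, fry called 3, and the exact permutation gave a smallest adjusted p of 0.0694. The macrophage list fell at the preset correlation (camera adjusted p = 1.13e-22), a call that was lost with an estimated correlation (adjusted p = 0.132). Of its 23 tested members, 18 were lower when adjusted over the list alone and 3 over all genes (Mrc1, Ms4a7 and Csf1r), 0 were higher, and 5 did not pass. The list mean was 7.76 ± 0.27 in Vehicle and 6.92 ± 0.29 in CSF1Ri tumours, a mean log2 fold change of -0.85 (median -1.06), and every CSF1Ri tumour lay below every Vehicle tumour. Siglec1, a sialoadhesin of tissue macrophages, was at 5.53 ± 0.46 in Vehicle tumours and was detected on 0 of 6 CSF1Ri arrays (at least 1.68-fold lower, adjusted p = 0.0939 over all genes). For the macrophage list fry gave adjusted p = 0.0387 and the exact permutation p = 0.0159 (adjusted p = 0.0794 over the 35 lists). The mean was -0.67 within the dimmer and -0.88 within the brighter arrays.

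The monocyte list fell as well, with 5 of 8 members lower when adjusted over the list alone, 2 of them over all genes (Cx3cr1 and Clec4a1). Its mean log2 fold change was -1.03, from 8.43 ± 0.20 to 7.40 ± 0.39. This was the only list called with an estimated correlation (adjusted p = 0.0273), and its camera adjusted p was 1.39e-10, its fry adjusted p 0.000966 and its exact permutation p 0.0159 (adjusted p = 0.0794). The transglutaminase gene F13a1 had a log2 fold change of -1.27 and Lst1 of -1.30, both with adjusted p = 0.177 over all genes. The mean was -0.92 within the dimmer and -1.13 within the brighter arrays.

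In the complement list, 5 of 9 members were lower and 1 was higher when adjusted over the list alone, and 1 (C6) was lower over all genes. The C1q genes C1qa, C1qb and C1qc, made mainly by macrophages and also members of the macrophage list, had log2 fold changes of -1.53, -1.40 and -1.43. The higher member was C4b (0.73), which was named after its value was seen. The list mean was -0.58 (camera adjusted p = 0.000671, but adjusted p = 0.373 with an estimated correlation), and -0.31 within the dimmer arrays. The colony-stimulating factor axis had 3 of 7 members lower when adjusted over the list alone, Csf1r and Spi1 (both also over all genes) and the GM-CSF receptor gene Csf2ra (-1.04, and -0.59 within the dimmer arrays). Its mean was -0.48 (camera adjusted p = 0.000315, adjusted p = 0.196 with an estimated correlation), and -0.24 within the dimmer arrays.

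Other myeloid lists were mixed. Among alternatively activated and suppressive macrophage genes, 1 of 17 passed when adjusted over the list alone, the lectin gene Clec10a (-1.08), while Ido1, which degrades tryptophan, was at 0.47, Ccl24 at -0.88 and Mgl2 at -1.44. Among proinflammatory cytokines and costimulators, 2 of 11 were lower when adjusted over the list alone, Osm (-0.77) and Il1b (-1.05). The myeloid chemokines had 3 of 16 lower when adjusted over the list alone, Ccl12, the platelet factor gene Pf4 (-1.23) and Ccl9 (-1.06), and 1 higher, the neutrophil attractant Cxcl1 (0.87), and only Ccl12 passed over all genes. In the lysosome list, 1 of 19 passed when adjusted over the list alone, the acid phosphatase gene Acp5 (-1.20). Clec10a was detected on 2 and Acp5 on 1 of 6 CSF1Ri arrays. The 4 list means were -0.25, -0.29, -0.26 and -0.18 with camera adjusted p of 0.0302, 0.0255, 0.0495 and 0.0189. With an estimated correlation the adjusted p was 0.199, 0.447, 0.558 and 0.435. Each call was lost on leaving out single tumours. For the suppressive list these were CSF1Ri 2 and 4 and Vehicle 2, 3 and 4 (means -0.22 to -0.20), for the proinflammatory list CSF1Ri 2, 4 and 5 and Vehicle 2, 3 and 4 (-0.30 to -0.23), for the chemokines the same 6 (-0.25 to -0.17), and for the lysosome list CSF1Ri 2 and 5 and Vehicle 2 and 4 (-0.17 to -0.12). The chemokine mean was -0.42 without Vehicle 1 and -0.40 without CSF1Ri 3, and within the dimmer arrays the chemokine and lysosome means were -0.02 and -0.06. The conventional dendritic cell list (mean -0.15, 5 members) and the macrophage lipid handling list (mean -0.01, median 0.06, 7 members) had 0 members past the threshold and camera adjusted p of 0.190 and 0.755.

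The neutrophil list fell by 1.31 on the log2 scale, from 7.57 ± 0.55 to 6.26 ± 0.68, with 10 of 17 members lower when adjusted over the list alone and 2, Mmp9 and Trem1, over all genes. For this list camera gave an adjusted p of 1.67e-13 and the call was lost with an estimated correlation (adjusted p = 0.152). Next by p were the decoy receptor gene Il1r2 (-0.89) and Mpo, the myeloperoxidase of granules (-2.78, from 8.33 ± 1.51 to 5.55 ± 1.30, adjusted p = 0.294 over all genes). Il1r2 was detected on 2 and Mpo on 3 of 6 CSF1Ri arrays. The exact permutation p of the list mean was 0.0317 (adjusted p = 0.111). The groups overlapped, since CSF1Ri 3 (7.31) lay above Vehicle 2 (6.92). Vehicle 1 had the highest neutrophil mean (8.24) and also the highest erythroid mean (10.12, against 6.48 to 8.84 in the other tumours). The erythroid list had a mean log2 fold change of -0.45, 0 of 6 members past the threshold (Car1 at -0.54, and 0.12 without Vehicle 1) and a camera adjusted p of 0.164. Its mean was 0.28 without Vehicle 1, and it was called without Vehicle 2 (-0.85), Vehicle 3 (-0.78) or CSF1Ri 3 (-0.80) and with the acinar covariate (-0.88). It was -0.13 within the dimmer and -0.95 within the brighter arrays. The neutrophil mean was -1.07 within the dimmer and -1.69 within the brighter arrays.

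In the list of mast cells, basophils and eosinophils, 0 of 9 members passed, with the tryptase gene Tpsab1 at -1.25 (-0.73 within the dimmer arrays). Its mean was -0.42 and its median -0.64 (camera adjusted p = 0.00982, adjusted p = 0.435 with an estimated correlation). The mean was -0.15 and the call was lost without Vehicle 4 (adjusted p = 0.158), and without CSF1Ri 4 it was -0.31 (adjusted p = 0.0545). It was -0.04 within the dimmer and -0.76 within the brighter arrays. The highest Vehicle tumour, Vehicle 4 (7.39), is only in the brighter set, and the highest CSF1Ri tumour, CSF1Ri 3 (6.71), only in the dimmer set.

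The 2 interferon lists had positive means, with 0 members past the test over all genes. In the interferon gamma response list, 13 of 16 members were higher when adjusted over the list alone and 0 over all genes, and all 16 log2 fold changes were positive. The list mean was 9.54 ± 0.55 in Vehicle and 10.23 ± 0.13 in CSF1Ri tumours (log2 fold change 0.69). Examples were Wars, a tryptophanyl-tRNA synthetase (0.62), the immunity-related GTPase genes Irgm2 (0.85) and Irgm1 (0.67) and the guanylate-binding protein gene Gbp5 (0.89). In the type I interferon list, 5 of 24 were higher when adjusted over the list alone and 0 over all genes, with a mean of 0.48 (7.07 ± 0.30 against 7.55 ± 0.15). Usp18, a feedback regulator of interferon signalling, was at 0.83, Cmpk2 at 0.89 and the nucleic acid sensor gene Zbp1 at 1.17. Oas3 was detected on 0 of 6 Vehicle arrays and was at least 1.13-fold higher in CSF1Ri tumours (adjusted p = 0.337 over all genes).

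The camera adjusted p was 5.97e-13 for the interferon gamma response list and 9.66e-12 for the type I interferon list, and both calls were lost with an estimated correlation (adjusted p = 0.184 and 0.169). For type I interferon and for the interferon gamma response, every CSF1Ri tumour lay above every Vehicle tumour, and the exact permutation p was 0.00794, the smallest possible (adjusted p = 0.0694). Vehicle 1 had the lowest mean of both lists, and without it the interferon gamma response mean was 0.43 and the type I interferon mean 0.33, with camera adjusted p of 6.56e-10 and 1.34e-07. Within the dimmer and brighter arrays the means were 0.82 and 0.81 for the interferon gamma response and 0.57 and 0.55 for type I interferon.

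The list of MHC class I antigen presentation was called higher by camera at the preset correlation (adjusted p = 9.65e-07) but not with an estimated correlation (adjusted p = 0.333) or with fry (adjusted p = 0.230). Of its 17 members, 0 passed even when adjusted over the list alone. All 17 log2 fold changes were positive, with a mean of 0.38 (10.29 ± 0.43 against 10.67 ± 0.08). Tapbp (0.64, and 0.26 within the brighter arrays) and Tap2 (0.72), which load peptide onto class I molecules, and the class I gene H2-Q7 (0.63, and 0.42 without Vehicle 1) were the first by p. The exact permutation p was 0.0159 (adjusted p = 0.0794). Vehicle 1 was the lowest tumour, and without it the mean was 0.17 (camera adjusted p = 0.00671). The mean was 0.54 within the dimmer and 0.40 within the brighter arrays. The MHC class II list gave no call (mean 0.10, camera adjusted p = 0.642), and its mean ran from -0.22 (without Vehicle 1) to 0.26 on leaving out each tumour. In it, 2 of 11 members were lower when adjusted over the list alone, the lysosomal reductase gene Ifi30 (-0.92) and the cathepsin gene Ctss (-0.74), while the class II transactivator gene Ciita was at 0.69 (0.26 without Vehicle 1).

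**Figure D2:**
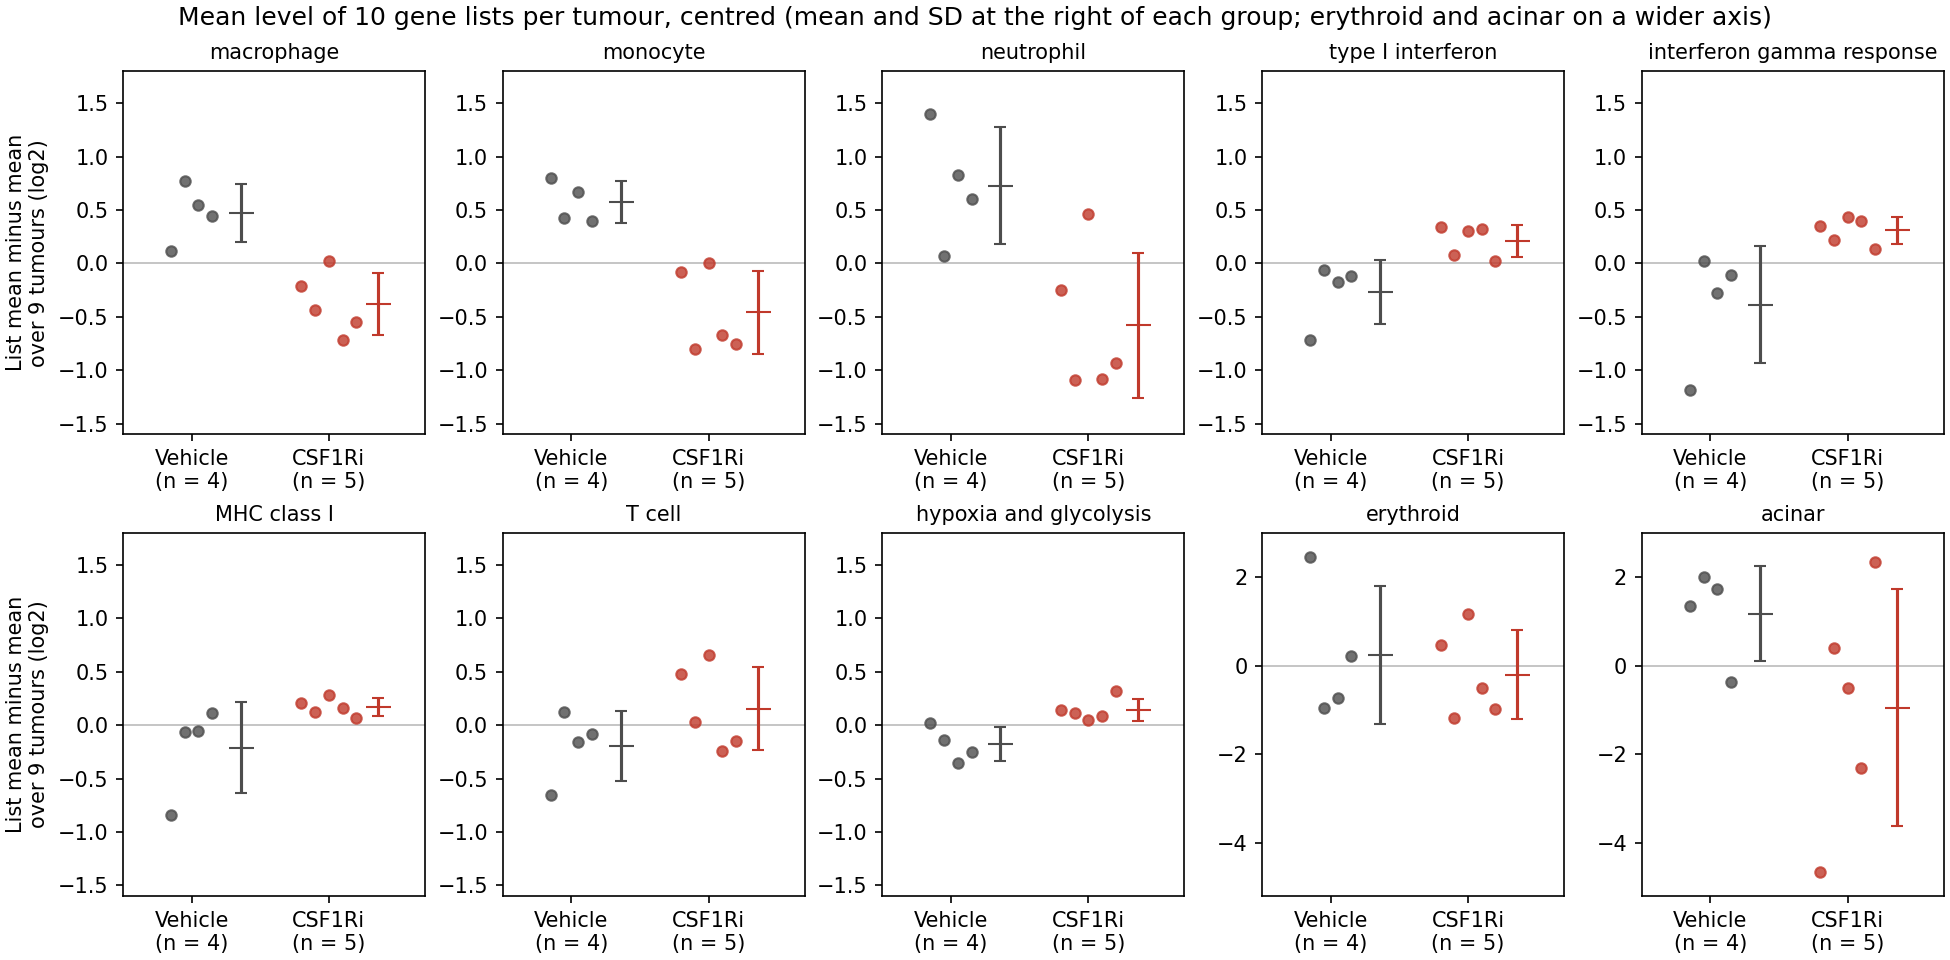
Mean of each of 10 gene lists per tumour minus its mean over the 9 tumours (y axis, log2), for Vehicle (grey, n = 4) and CSF1Ri (red, n = 5), with the mean and SD beside each group. Vehicle 1 is the lowest point of both interferon lists and the MHC class I list, and the acinar means span from 5.33 to 12.33 before centring.

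The T cell list had a positive mean within the spread of the tumours. The mean of 12 members was 6.48 ± 0.33 in Vehicle and 6.83 ± 0.39 in CSF1Ri tumours (log2 fold change 0.35). Of these, 0 passed when adjusted over the list alone or over all genes, with the kinase gene Zap70 at 0.62 (adjusted p = 0.621, 0.37 without Vehicle 1) and the T cell receptor subunit gene Cd3e at 0.81 (adjusted p = 0.663, 1.48 within the dimmer arrays). The camera adjusted p was 0.00454, the adjusted p was 0.435 with an estimated correlation, and the exact permutation p was 0.222. The call was lost without Vehicle 1 (mean 0.20, adjusted p = 0.0989), without CSF1Ri 3 (mean 0.23, adjusted p = 0.0889), without the filter on dim probes and with the acinar list as a covariate. The mean was 0.63 within the dimmer and 0.32 within the brighter arrays. CSF1Ri 1 (7.16) and CSF1Ri 3 (7.33) had the highest T cell means. The other CSF1Ri tumours lay between 6.44 and 6.71, inside the Vehicle range of 6.02 to 6.80.

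The other lymphoid lists gave no call. The mean was 0.28 for cytotoxic T and NK cell genes (camera adjusted p = 0.0594, 0 of 9 members), with Xcl1 at -0.51, Klrd1 at 0.65 (0.40 without Vehicle 1) and Ifng at 0.68, and it was 0.31 for B and plasma cell genes (camera adjusted p = 0.120, 0 of 7). Xcl1 was detected on 1 of 6 CSF1Ri arrays. The cytotoxic list was called without Vehicle 2 (0.42), CSF1Ri 4 (0.34) or CSF1Ri 5 (0.34), and its mean was 0.13 without Vehicle 1 (adjusted p = 0.452), 0.19 without CSF1Ri 3, 0.19 with the acinar covariate and 0.44 within the dimmer arrays. The B and plasma cell list was called without Vehicle 4 (0.45), CSF1Ri 2 (0.46), CSF1Ri 4 (0.42) or CSF1Ri 5 (0.44), and its mean was 0.11 without CSF1Ri 1, 0.13 without CSF1Ri 3, -0.05 with the acinar covariate and 0.77 within the dimmer arrays. As for T cells, CSF1Ri 1 and CSF1Ri 3 were highest for cytotoxic (6.79 and 6.82) and B and plasma cell genes (7.24 and 7.12). For cytotoxic genes the other CSF1Ri tumours lay from 6.21 to 6.29 and Vehicle from 5.73 to 6.61. For B and plasma cell genes these ranges were 5.84 to 5.98 and 5.84 to 6.51. In the immune checkpoint list (mean 0.08, median -0.00, camera adjusted p = 0.755), 1 of 12 members was higher when adjusted over the list alone, the costimulatory receptor gene Tnfrsf9 (0.80, adjusted p = 0.164 over all genes). Cd274, which encodes PD-L1, was at 9.32 ± 0.87 in Vehicle and 10.19 ± 0.43 in CSF1Ri tumours (adjusted p = 0.617), a log2 fold change of 0.87 that was 0.49 without Vehicle 1.

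Among matrix proteases and inhibitors, 3 of 17 were lower when adjusted over the list alone, Mmp9, Ctsk and the collagenase gene Mmp13 (-0.79, with its 2 probes differing in sign), and Mmp9 and Ctsk also over all genes. The list mean was -0.45 but its median -0.10 (camera adjusted p = 0.00247, adjusted p = 0.324 with an estimated correlation, exact permutation p = 0.00794). The call was lost without Vehicle 2 (mean -0.37, adjusted p = 0.0533). The collagen and matrix list had 0 of 21 members past the threshold and a mean of -0.16 (camera adjusted p = 0.0312, adjusted p = 0.558 with an estimated correlation). That call was lost without Vehicle 2, Vehicle 4, CSF1Ri 1, CSF1Ri 2 or CSF1Ri 4, the mean was -0.08 without Vehicle 2 and -0.10 without Vehicle 4, and it was -0.24 without Vehicle 1 and -0.25 without CSF1Ri 3. The elastin gene Eln was at -0.62.

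Stromal and epithelial lists gave no call. Cancer-associated fibroblast genes had a mean of -0.06 (camera adjusted p = 0.325), with 0 of 18 members past the threshold and the smooth muscle gene Tagln at -0.62, and without Vehicle 1 or CSF1Ri 3 the list was called at -0.22 and -0.21, while its mean was 0.05 without Vehicle 2. Endothelial genes had a mean of -0.02 (camera adjusted p = 0.529), called at -0.14 without CSF1Ri 3. Ductal and tumour epithelial genes had a mean of 0.23 (camera adjusted p = 0.0755), with 0 of 15 members past the threshold and the claudin gene Cldn4 at 0.82 (0.52 without CSF1Ri 3, 0.39 within the brighter arrays), and were called without Vehicle 1 (0.29), Vehicle 3 (0.28), CSF1Ri 1 (0.32) or CSF1Ri 4 (0.30) and with the acinar covariate (0.40, adjusted p = 0.000766). The epithelial mean was 0.14 without CSF1Ri 3 and -0.00 within the brighter arrays. In the mesenchymal transition list (mean -0.02, median 0.08, camera adjusted p = 0.764), 1 of 12 members was lower when adjusted over the list alone, Tgfbi (-0.63).

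Genes of acinar cells, the enzyme-secreting cells of the normal pancreas, varied widely between tumours of the same group. The mean of 24 genes was 11.17 ± 1.07 in Vehicle and 9.05 ± 2.67 in CSF1Ri tumours, from 5.33 in CSF1Ri 1 to 12.33 in CSF1Ri 5. All 24 log2 fold changes were negative (mean -2.12), and 0 passed when adjusted over the list alone. The chymotrypsin-like gene Ctrl was at -2.60 and the elastase gene Cela3b at -2.93 (-1.85 without CSF1Ri 1). Camera gave an adjusted p of 7.79e-10, the adjusted p was 0.415 with an estimated correlation and the exact permutation p was 0.206, so the difference lay within the spread between tumours. On leaving out each tumour the mean ran from -2.94 (without CSF1Ri 5) to -1.19 (without CSF1Ri 1), and it was -3.28 within the dimmer and -2.45 within the brighter arrays. With the acinar list mean as a covariate, 8 of the 21 genes were called, and the macrophage, type I interferon, interferon gamma response and MHC class I means were -0.87, 0.38, 0.62 and 0.32. Islet genes had a mean of -0.05 (camera adjusted p = 0.755) and were called at -0.31 without CSF1Ri 3.

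**Figure D3:**
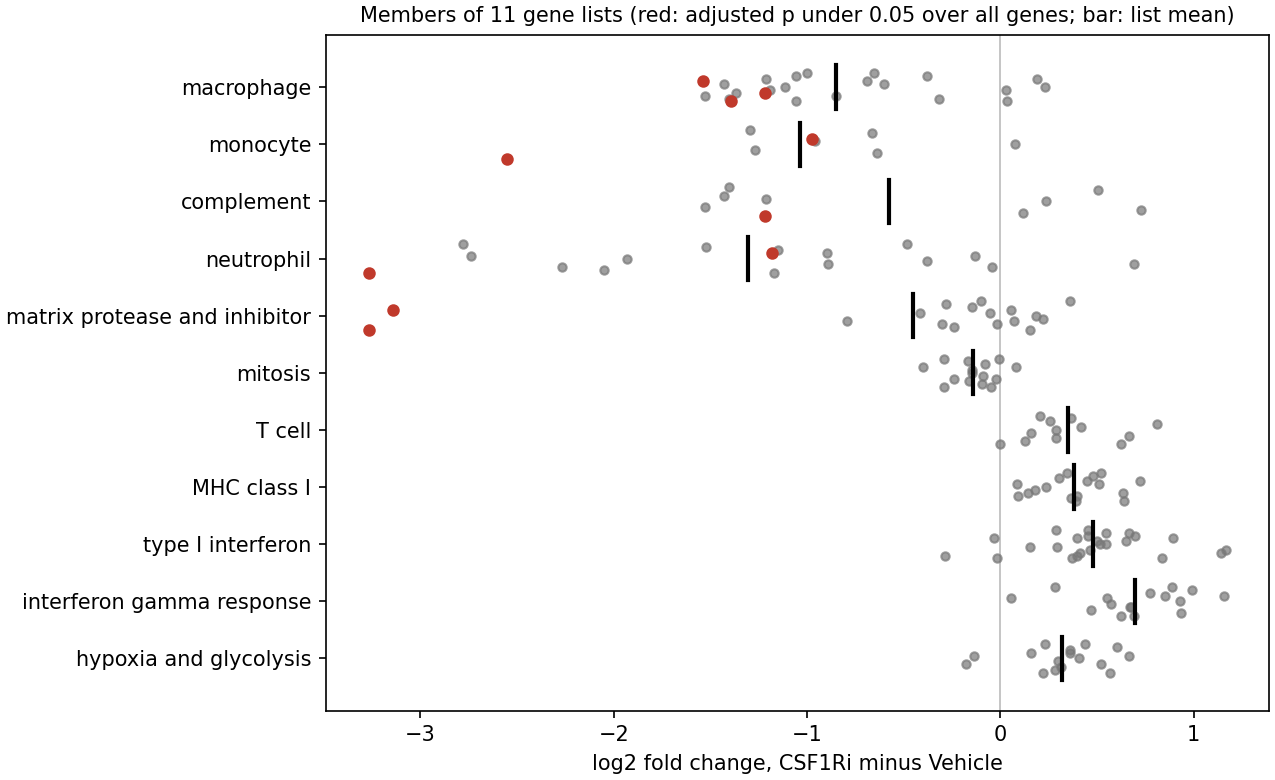
Log2 fold change, CSF1Ri minus Vehicle (x axis), of each tested member of 11 gene lists (y axis), with a bar at the list mean and genes past an adjusted p of 0.05 over all genes in red. The called genes lie to the left, down to -3.27 for Mmp9, and the interferon gamma response mean is at 0.69.

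The hypoxia and glycolysis list was called higher by camera at the preset correlation (adjusted p = 3.72e-09), and the call was lost with an estimated correlation (adjusted p = 0.132). Of its 16 members, 9 were higher when adjusted over the list alone and 0 over all genes. The mean was 9.92 ± 0.16 in Vehicle and 10.24 ± 0.10 in CSF1Ri tumours (log2 fold change 0.32). Among the members that passed were the collagen prolyl hydroxylase genes P4ha2 (0.57) and P4ha1 (0.52), the triosephosphate isomerase gene Tpi1 (0.36) and the hypoxia-responsive gene Ndrg1 (0.44). For this list fry gave adjusted p = 0.0387, and the exact permutation p was 0.00794 (adjusted p = 0.0694). The mean was 0.25 within the dimmer and 0.38 within the brighter arrays.

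The cell-cycle and respiratory lists had small negative means. These were -0.14 for mitosis (15 members), -0.11 for DNA replication (18 members) and -0.09 for oxidative phosphorylation (22 members), with 0 members of any of the 3 past the threshold when adjusted over the list alone, and Melk at -0.29. Camera adjusted p was 0.00853, 0.0111 and 0.0130, and the adjusted p was 0.466, 0.152 and 0.324 with an estimated correlation. The mitosis call was lost without Vehicle 3 (-0.10), Vehicle 4 (-0.12) or CSF1Ri 2 (-0.10) and the mean was -0.23 without Vehicle 1. The DNA replication call was lost without Vehicle 3 (-0.10) or CSF1Ri 2 (-0.09), and the oxidative phosphorylation call without Vehicle 3 (-0.08) or Vehicle 4 (-0.06). Within the brighter arrays the mitosis mean was -0.05, and within the dimmer arrays the oxidative phosphorylation mean was -0.05. Ribosomal protein genes (mean -0.02, camera adjusted p = 0.498) and genes of tissue dissociation and immediate early response (mean -0.00, median 0.12, camera adjusted p = 0.642) gave no call.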

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

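The splits of the tumours, the fit with the acinar mean and the fits that leave out a tumour were planned, while the intervals and permutation tests built on those fits and the other tests in this part were chosen only after the result was seen, as were the final rules for reading the 3 covariate tests and the test of an equal loss of cells.

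In 244 groups of 4 or 5 tumours, the highest or lowest tumour stood far from the rest of its group 14 times, where chance alone gives about 1 in 20, or 12.2. Vehicle 1 stood low for Ms4a7 (8.717, the others 9.61 to 9.70), Zbp1 (6.119, the others 7.38 to 7.54) and Cxcl1 (6.786, the others 7.72 to 7.87). It also stood low for the mean of alternatively activated and suppressive macrophage genes (7.75, the others 8.11 to 8.17) and of mitosis genes (8.249, the others 8.57 to 8.64). CSF1Ri 3 stood high for Tagln (6.644, the others 5.86 to 6.05), Eln (8.628, the others 7.45 to 7.60), the cancer-associated fibroblast mean (8.913, the others 8.12 to 8.19) and Enpp5 (7.457, the others 7.13 to 7.23). CSF1Ri 2 stood high for Ccl12 (6.133, the others 5.47 to 5.62) and low for H2-Q7 (8.682, the others 9.17 to 9.37). CSF1Ri 1 stood low for Siglec1 (4.462, the others 4.54 to 4.56), where no CSF1Ri array detected the gene. Vehicle 3 stood high for Gphb5 (4.74, the others 4.45 to 4.49) and Vehicle 4 for Prss35 (6.252, the others 5.69 to 5.78).

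For the genes, 1 of 100 splits of the 9 tumours into 4 and 5, the real split itself, gave as many genes past the threshold. The real count was 21 and the highest of the others 10, in a split that exchanges Vehicle 1 and CSF1Ri 3. Chance is therefore unlikely to account for the gene count, though with 100 splits the smallest share possible is 1 in 100. For the lists chance stays open. With camera at the preset correlation, 7 of 100 splits gave as many lists as the real one, which gave 21, and the highest of the others gave 26. The median of the other splits was 10 lists, so a list call at that setting is weak evidence by itself.

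The fall of the macrophage list was set against 3 technical or compositional explanations. A different amount of normal pancreas was argued against as the whole cause by a difference of -0.87 (95% interval -1.44 to -0.30) with the acinar mean in the fit, against -0.848 (-1.30 to -0.40) without it. The brightness of the arrays was argued against by a difference of -0.671 in the dimmer set and -0.876 in the brighter set, with the groups apart in both. The sets share Vehicle 1, Vehicle 3 and CSF1Ri 1 and are not independent. An equal loss of cells that carry all the listed genes in a fixed ratio stays open: the members' differences spread more in the real split than in any other (exact permutation p = 0.00794, SD 0.569 against at most 0.495), also among the 9 members brighter than the median gene (exact permutation p = 0.00794), but members that other cells also carry would fall less under such a loss too. Fewer macrophages and lower expression per macrophage therefore cannot be told apart in whole-tumour RNA.

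The rise of the interferon and MHC class I lists, averaged, was 0.518 (exact permutation p = 0.00794). Vehicle 1 as the whole cause was argued against, since the difference was 0.31 without it (exact permutation p = 0.0357 of 56 splits). With the acinar mean in the fit the difference was 0.441. The type I interferon, interferon gamma response and MHC class I lists kept their camera calls at the preset correlation (adjusted p = 7.55e-08, 1.74e-10 and 0.000194). Calls at that setting are weak evidence by themselves. Without the covariate, camera with an estimated correlation did not call these lists (adjusted p = 0.169, 0.184 and 0.333). CSF1Ri 5, which had the highest acinar mean (12.33), still lay above every Vehicle tumour for both interferon lists. For MHC class I, CSF1Ri 5 lay below Vehicle 4 (10.569 against 10.615). The interval with the acinar mean (-0.12 to 1.01) included 0, where it had been 0.0596 to 0.976, so a contribution of normal pancreas stays open.

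The fall of the neutrophil list was -1.31 (interval -2.30 to -0.314). With the erythroid mean in the fit the difference was -1.12 (-1.70 to -0.528). This argued against blood left in the tumours as the whole cause, as far as the erythroid mean tracks blood. The erythroid mean was far the highest in 1 tumour, Vehicle 1 (10.12, the others 6.48 to 8.84). Without Vehicle 1 the neutrophil list was at -1.08 and the erythroid list at 0.28. The fall did not rest on Mmp9 and Trem1, which macrophage-lineage cells also carry, since the other 15 genes differed by -1.18 (exact permutation p = 0.0476). A smaller number of neutrophils and lower expression per cell both stay open as hypotheses, and no test here separates them.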

How the results depend on the processing

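The alternatives by array brightness were chosen after seeing the data, and all others were planned. The slide as a block was planned and not run, because the files and labels name no slide. Of 2150 values of the named genes over the alternatives, 1952 kept their direction and side of the threshold, 154 lost a call, 43 gained 1 and 1 reversed: Car1, uncalled throughout, ran from -0.83 to 0.12 on leaving out each tumour and was positive without Vehicle 1. All 154 losses fell on the 21 genes called in the main fit, because the other named genes had no call to lose. Spi1 lost its call in 17 of 24 alternatives, Oscar in 16 of 24 and Csf1r in 13 of 25, while Cx3cr1 lost it in 0 of 24. The median log2 fold change of all genes stayed under 0.1 in size under every scaling. The 21 changed genes became 13 without the filter on dim probes (19057 genes tested), 10 with probes detected on all 12 arrays, 45 with the tumour as a random block over 12 arrays, 44 with array weights, 8 with the acinar mean as a covariate, 34 at an adjusted p under 0.10, and 11 to 34 on leaving out each tumour. They became 52 with array brightness as a term beside that random block, 1 in the dimmer arrays only and 11 in the brighter arrays only, where fewer tumours were compared. For the other changes the cause was not tested. Against 21 of the 35 lists, 11 of the 35 were called in the dimmer arrays, 1 with an estimated correlation (monocyte), 3 with fry and 0 with the exact permutation, where 10 had an unadjusted p under 0.05. The macrophage mean (-0.85) had adjusted p of 0.132 with an estimated correlation and 0.0794 by exact permutation. For type I interferon (0.48) the values were 0.169, 0.0789 with fry and 0.0694, for MHC class I (0.38) 0.333, 0.230 and 0.0794, and for T cells (0.35) 0.435, 0.417 and 0.389. The T cell mean was 0.20 without the filter (adjusted p = 0.0641), 0.25 with the acinar covariate, and 0.20 to 0.46 on leaving out each tumour. Direction and camera call at the preset correlation held in all 25 alternatives for a set of lists. These were the macrophage, monocyte, neutrophil, type I interferon, interferon gamma response, MHC class I, and hypoxia and glycolysis lists. Signal over background limits the dim genes, whose folds depend on the background correction and its offset.

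Vehicle and CSF1Ri tumours share replicate numbers, and the labels do not say whether the numbers pair them. Same-number correlations were -0.09, 0.03, 0.12 and 0.34, and 0 of 4 Vehicle tumours correlated best with its own number. These values gave little sign of a pairing but do not settle it. The main fit was unpaired. With the replicate block, 1 gene was called (Cx3cr1), in a fit that has fewer residual degrees of freedom. CSF1Ri 5 has no Vehicle tumour of its number, so it adds nothing to the group difference in that fit. Leaving out CSF1Ri 5 without the block gave 12 called genes.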

Other observations

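The test of osteoclast-associated genes in this part was chosen only after the result was seen.

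Genes with higher values in CSF1Ri tumours did not pass the limma test. Those given here were taken by the smallest unadjusted p, which favours genes whose groups do not overlap. A lack of overlap is therefore no further support for them. Over all tested genes the groups did not overlap for 139 lower and 143 higher genes, 2.88% against 1.59% by chance. Itpk1, an inositol phosphate kinase gene, was at 9.17 ± 0.12 in Vehicle and 9.81 ± 0.13 in CSF1Ri tumours (adjusted p = 0.0556). The organic anion transporter gene Slco3a1 was at 8.47 ± 0.34 and 9.36 ± 0.14 (adjusted p = 0.0753), and the calcium channel gene Cacna1h at 6.57 ± 0.55 and 7.71 ± 0.29 (adjusted p = 0.140). The log2 fold changes of the kept probes of Slco3a1 ran from 0.16 to 0.89. Other log2 fold changes were 0.53 for Enpp5, 0.55 for Gphb5 (detected on 1 of 6 Vehicle arrays), 0.54 for the homeobox gene Hhex, 0.47 for Fam207a, 0.47 for the Golgi GTPase gene Rab6a and 0.45 for the glycogen enzyme gene Pgm1, with no overlap of groups. The other kept probe of Fam207a was at 0.05, and the kept probes of Rab6a ran from 0.18 to 0.56. Prss35 was at 0.85 with overlapping groups.

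Ctsk, Mmp9, Oscar, Slc9b2, Acp5 and the creatine kinase gene Ckb (-1.76, adjusted p = 0.140) are known from osteoclasts, which arise from the same precursors as macrophages. The hypothesis was that the wider set of osteoclast-associated genes would be lower too. Of 19 further genes 13 were tested, 8 had a lower mean in CSF1Ri tumours, and their mean differed by -0.10 (exact permutation p = 0.0476). No gene of the 13 passed over all genes, with the proton-pump gene Tcirg1 at -0.57 and the integrin gene Itgav at 0.26. Several are proton-pump genes of any lysosome, and the lysosome list was itself at -0.18. The result is consistent with a small fall of the set but does not point to a cell type, while the 6 prompting genes were at -3.27 to -1.20.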
